A study of Homo sapiens with 8 samples.

How the data were processed

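The series probed the structure of RNAs that co-purify with SNU13, a protein that the labels name by its size in kilodaltons and that binds kink-turns, the sharply bent motif formed by boxes C and D of box C/D small nucleolar RNAs (snoRNAs). Per the labels' protocols, HEK293T cells, a human embryonic kidney line, stably overexpressed FLAG-tagged SNU13. RNA-protein complexes were pulled down from lysate with an anti-FLAG antibody, and the RNA was treated while still on the beads. NAI-N3 is a SHAPE reagent that acylates the 2'-hydroxyl group of flexible nucleotides, and DMSO, its solvent, served as the untreated control. The 8 samples form a group of 4 NAI-N3 libraries and a group of 4 DMSO libraries, numbered 1 to 4 in each. The labels do not say whether the numbers stand for separate cultures. Adaptors were ligated to both RNA ends, and ribosomal RNA, spliceosomal snRNA and some abundant snoRNAs were depleted with RNase H. Reverse transcription was run so that adducts are read as mutations (mutational profiling), and small RNA libraries were amplified. The depletion step removes abundant RNAs from view, and the pull-down selects RNAs bound by the tagged protein, so the values describe RNAs in or near such complexes and not the whole cell.

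The authors deposited 1 reactivity score per nucleotide for the whole series, with the base, strand and genome position of each nucleotide. The score has no stated scale. It was below 0 at some nucleotides. Whether and how the DMSO signal was subtracted, any normalization, the depth minimum and the way the 8 libraries were combined were not given in the sources used here. Per the submitters' processing notes, cutadapt 3.4 and STAR (version not given in the sources used here) were used with genome build hg38; the notes give them no roles. No value of a single library was used here, the sequencing depth behind each score was unknown, and the spread between the replicates could not be measured. The planned test of NAI-N3 against DMSO, with and without the replicate number as a block, was therefore not run. Errors given here are standard deviations (SD) over RNAs or over nucleotides. The RNAs are not biological replicates, and each p-value describes these profiles only.

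Profiles were read as deposited, in the 5' to 3' direction of each RNA, and coordinates are 1-based on hg38. Gene names came from RefSeq gene spans of the same assembly and were assigned by overlap of position alone, without regard to strand or exons. Box C was the best match to RUGAUGA (R is A or G) with at most 2 mismatches and UGA at positions 2 to 4. Box D was the best match to CUGA with at most 1 mismatch and GA at its end. Reverse order meant box D in the first 20 nt and box C in the last 20 nt, and forward order the opposite. Minimum free energy structures were predicted with ViennaRNA 2.7.2 from sequence alone, and each nucleotide was placed in a stem, a hairpin loop, an internal region (bulge, internal loop or multiloop) or the external region outside all stems. The predictions ignore bound protein and do not model kink-turns.

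For each RNA with at least 20 nt, the contrast of a box, of the terminal 5 nt at both ends or of the predicted unpaired nucleotides was its mean score minus the mean over the other nucleotides. For a base, it was the mean at that base minus the mean of the whole RNA, as fixed in advance. Bases were first set against the other bases by mistake, and the form was corrected after those results, in which C passed the threshold, had been seen. The median contrast over RNAs was compared with 10000 sets of random circular shifts of the profiles within their RNAs, a two-sided permutation test whose smallest p is 0.0002. Circular shifts keep the peaks and the runs of a profile together and move them relative to the sequence. Because profiles are skewed, the median over shifted sets is not exactly 0 and is given beside the observed value of each contrast in its main form. Box C position 2 was set against positions 3 and 4 with an exact sign-flip permutation test over all 16384 sign patterns of 14 RNAs. Adjusted p-values are Benjamini-Hochberg values over 5 tests of elements and, separately, 4 tests of bases. A paired-to-unpaired separation was also expressed per RNA as the area under the ROC curve (AUC), where 0.5 means none. The box rules, the tests and a first set of other settings were fixed before the data were examined, as was the rule to name all RNAs if at most 25 were listed.

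On simulated data, in which real profiles of the 14 RNAs (1279 nt) were rotated at random, the box C contrast test called 6% of 200 sets with no change, 20.5% when box scores were multiplied by 0.5 and 65.5% when multiplied by 0.2. The test thus has little power for an element scaled by 0.5. Rotation is also how the test forms its shifted sets, so the rate of calls with no change was set by design. It says nothing about an element that always lies at a low-signal end. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The other settings fixed in advance were medians in place of means, a cap at the 95th percentile of all scores, ranks within each RNA, a minimum of 40 nt, exact box matches, removal of 5 nt at each end, pairing from base-pair probabilities under 0.5, boxes held unpaired in the folding, A and U only, and 30 nt windows for the boxes. Added after the data were seen were exact zeros treated as not measured, the first 2 and last 2 nt treated as not measured, each RNA left out in turn, a box D of bktRNA1 further inside, boxes left out, G and C only, and each base against the other bases. Internal boxes and guide elements occurred in too few RNAs to test, and RNA classes could not be compared because all names were of 1 kind. Forward and reverse box orders were not compared because the RNAs that met the first rule also met the second.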

Results

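The data were 1 reactivity profile for each of 14 RNAs, named bktRNA1 to bktRNA385, covering 1279 nt from 39 nt (bktRNA2) to 251 nt (bktRNA1). Every listed nucleotide had a score (100%). Scores ran from -0.0257 to 0.169 with a median of 0.00127. Of all nucleotides, 748 lay above 0, 197 below 0, and 334 were exactly 0 (26.1%, Wilson 95% interval 23.8 to 28.6, which treats nucleotides as independent). The first 2 and last 2 nt were exactly 0 in all 14 RNAs, which made 56 of these zeros, and elsewhere 278 of 1223 nt (22.7%) were 0. Depth per nucleotide was unknown, so an exact 0 can stand for no reactivity or for a position that gave no estimate. As a floor from the profiles themselves, 246 nt (19.2%) had a score larger than the size of the most negative score of their own RNA.

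On hg38, 10 of the 14 RNAs lay within the span of a protein-coding gene. bktRNA1 (chromosome 10, 100237051 to 100237301, minus strand) lay in CWF19L1, and its nt 1 to 146 overlapped the span of the snoRNA gene SNORA12. bktRNA2 (chromosome 17, 8266548 to 8266586, plus) lay in PFAS, which encodes an enzyme of purine synthesis, and bktRNA4 (chromosome 17, 57317170 to 57317296, plus) in MSI2, an RNA-binding protein gene. bktRNA16 (chromosome 13, 36871107 to 36871166, minus) lay in SMAD9, bktRNA21 (chromosome 22, 46289013 to 46289068, plus) in TTC38, and bktRNA28 (chromosome 19, 56111825 to 56111871, minus) in ZNF787. bktRNA29 (chromosome 1, 162786277 to 162786330, plus) lay in DDR2, a collagen receptor gene, and bktRNA43 (chromosome 20, 49233772 to 49233852, plus) in the RNA helicase gene DDX27. bktRNA105 (chromosome 6, 149599700 to 149599903, minus) lay in KATNA1, a microtubule-severing enzyme gene, and bktRNA133 (chromosome 1, 156952195 to 156952331, minus) in ARHGEF11. No gene span overlapped bktRNA17 (chromosome 16, 67932332 to 67932390, minus), bktRNA23 (chromosome 19, 6602539 to 6602582, plus), bktRNA61 (chromosome 7, 135180215 to 135180280, minus) or bktRNA385 (chromosome 10, 38351943 to 38351996, plus). Whether the overlaps are exonic or intronic was not analysed here.

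In 13 of the 14 RNAs, box D lay at the 5' end and box C at the 3' end, the reverse of the order in box C/D snoRNAs. Box D was an exact CUGA starting at nt 4 in bktRNA4 and bktRNA17 and at nt 5 in the other 11. Box C lay in the last 20 nt of all 14 RNAs and matched RUGAUGA exactly in 12, with GUGAUGG in bktRNA1 and AUGAUGU in bktRNA17. bktRNA1 had no box D in its first 20 nt. The 3 RNAs that met the forward rule, bktRNA4, bktRNA29 and bktRNA385, also met the reverse rule, so the orders were not compared. The counts of 13 and 3 were the same with 30 nt windows. Whether the RNAs and their ends were chosen by these boxes was not examined here. If they were, the order and place of the boxes follow from that choice.

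Mean reactivity per RNA ranged from 0.00193 ± 0.00603 (SD over 47 nt) in bktRNA28 to 0.0110 ± 0.0216 (SD over 251 nt) in bktRNA1, with a median over RNAs of 0.00713. Each profile was uneven, with an SD above its mean. The highest score of the set, 0.169, was at the G at nt 128 of bktRNA1 (AUCAGAGAA), inside the span of SNORA12. In bktRNA4 the G at nt 45 reached 0.137, the A at nt 54 reached 0.117 and the A at nt 79 reached 0.113. The C at nt 36 reached 0.130 in bktRNA385 and 0.0684 in bktRNA29, the U at nt 31 of bktRNA16 reached 0.121, and the A at nt 31 of bktRNA17 reached 0.111. bktRNA2 peaked directly before its box D, at 0.0980 at the U of nt 4. bktRNA23 peaked at 0.0567 at the A of nt 3, the second nucleotide before its box D. bktRNA28 was the flattest profile, with a highest score of 0.0270 and 53.2% of its nucleotides at 0. Across the 14 RNAs, 41 nt scored above 0.05, a bound chosen after the data were seen, and they fell in 11 RNAs. No nucleotide passed it in bktRNA21, bktRNA28 or bktRNA133. bktRNA1 alone held 15 of the 41 in its nt 1 to 146 and 3 in the rest.

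**Figure D1:**
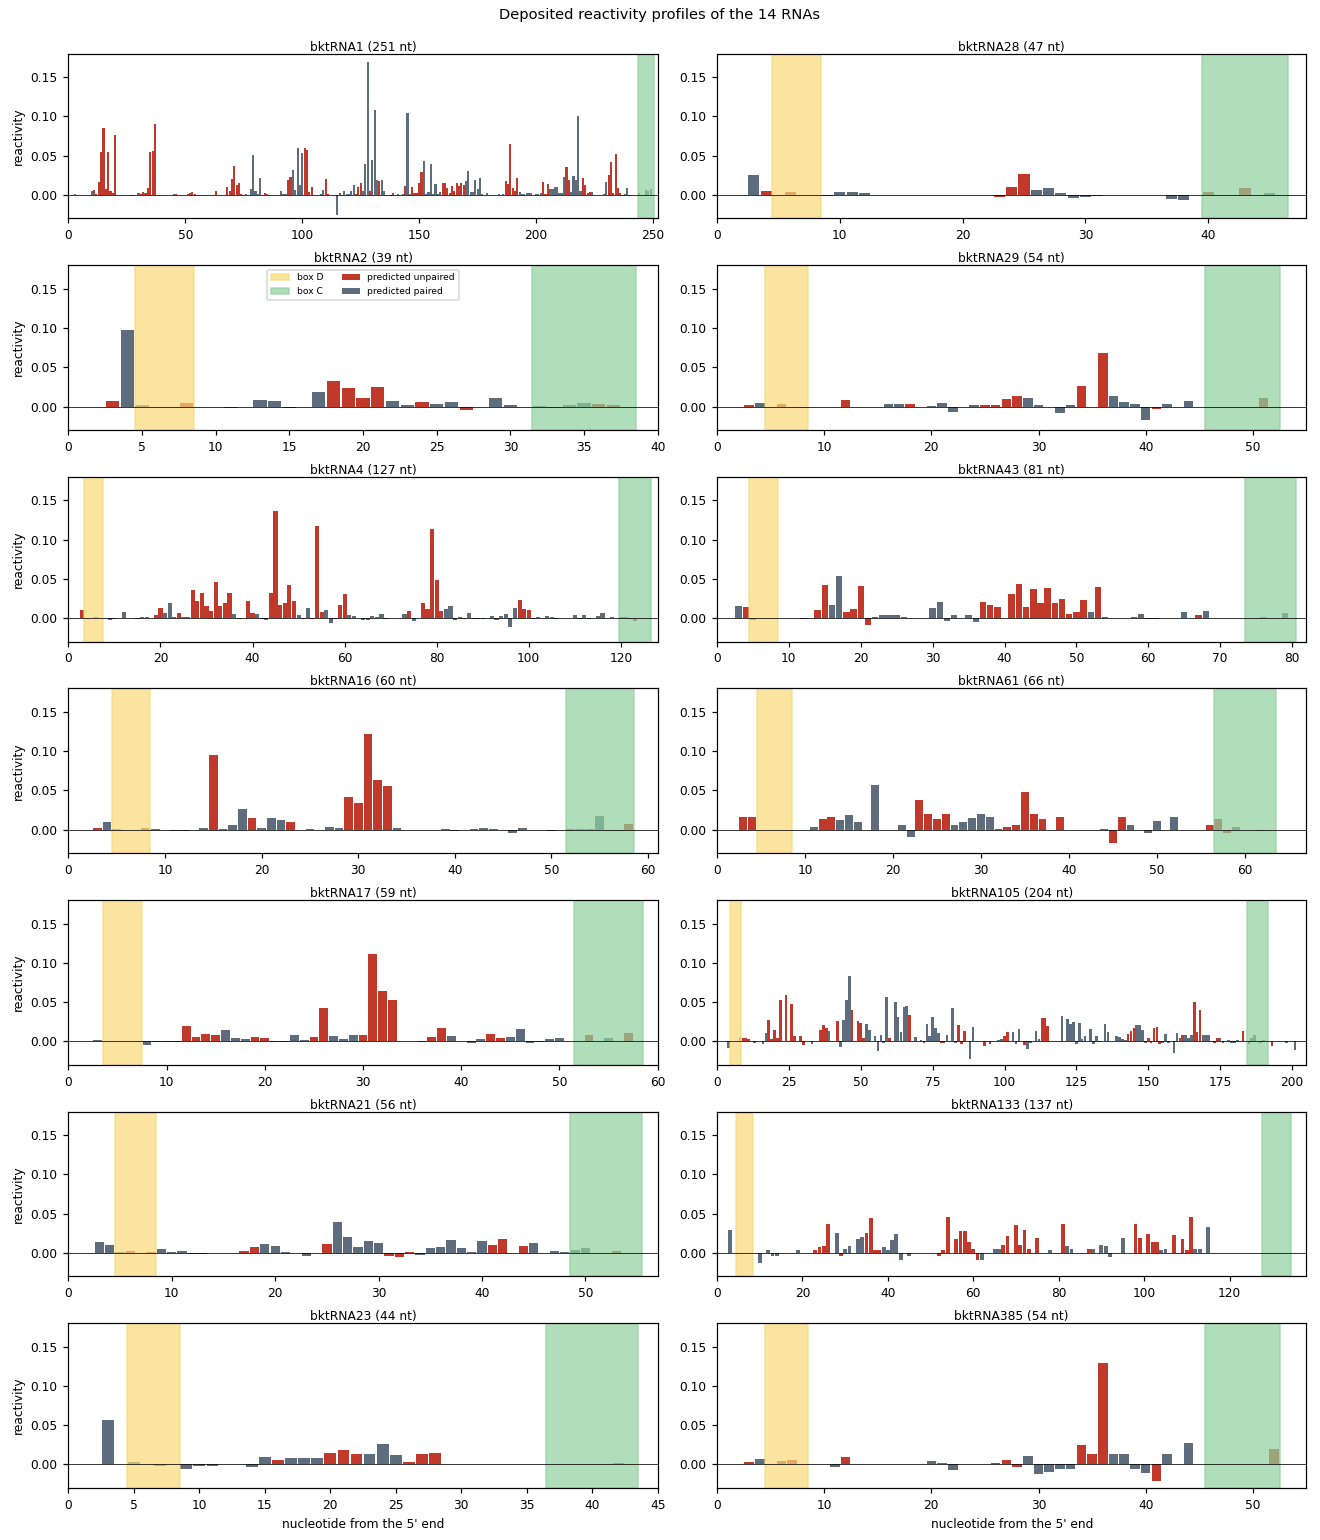
Reactivity score (y axis, no stated unit) at each nucleotide from the 5' end (x axis, nt) of the 14 RNAs, 1 bar per nucleotide, red where the predicted structure is unpaired and dark grey where it is paired. Yellow and green bands mark box D and box C, and none of the 41 nt above 0.05 lies in a band.

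The boxes that SNU13 binds in a kink-turn were compared with the rest of each RNA. Box C was less reactive than the rest in 13 of 14 RNAs. The largest gap was in bktRNA4, with a mean of -0.000155 over box C and 0.00927 elsewhere, and bktRNA1 had 0.00301 in box C and 0.0112 elsewhere. In bktRNA133 every box C nucleotide was listed at 0. The exception was bktRNA28, with 0.00214 in box C and 0.00190 elsewhere. Of the 98 box C nucleotides, 5 scored above 0.01, against 304 of all 1279 (23.8%). The highest were the last A of box C in bktRNA385 (0.0196) and the A of position 4 in bktRNA16 (0.0178).

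The median box C contrast was -0.00631 (SD over 14 RNAs 0.00273), where shifted profiles had a median of -0.00232 (permutation p = 0.0064, adjusted over 5 tests p = 0.0160). The call was lost when 5 nt were removed at each end (-0.00591, permutation adjusted p = 0.0977, range over all settings 0.0120 to 0.146), with ranks, with medians (-0.000639) and with zeros treated as not measured. It held when the always-zero end positions, which include 8 box C nucleotides, were treated as not measured (-0.00689, permutation adjusted p = 0.0120). Removing 5 nt at each end also took away part of box C in most RNAs.

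Box D was lower than the rest in all 13 RNAs that had it. Its mean was 0.000467 against 0.00963 elsewhere in bktRNA16 and 0.000462 against 0.00851 in bktRNA17, and all 4 of its nucleotides were listed at 0 in bktRNA61 and bktRNA133. No box D nucleotide of the 52 scored above 0.01, and the highest was 0.00539 in bktRNA105. The nucleotides before box D were higher. The mean was 0.0132 ± 0.0163 (SD, 13 RNAs, median 0.00744) at the second nucleotide before box D, 0.0129 ± 0.0264 (median 0.00754) at the nucleotide directly before it, and 0.000364 ± 0.00114 at the C of the box. bktRNA2 carried much of the mean directly before box D, which was 0.00580 ± 0.00698 over the other 12 RNAs. The first nucleotide after box D stayed at -0.000102 ± 0.00284.

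The median box D contrast was -0.00648 (SD over 13 RNAs 0.00271), against -0.00294 in shifted profiles (permutation p = 0.0200, adjusted p = 0.0333). The call was lost with ranks (permutation adjusted p = 0.113, range over all settings 0.0107 to 0.146) and with zeros treated as not measured (0.146). It held with medians, at a smaller contrast of -0.00101.

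**Figure D2:**
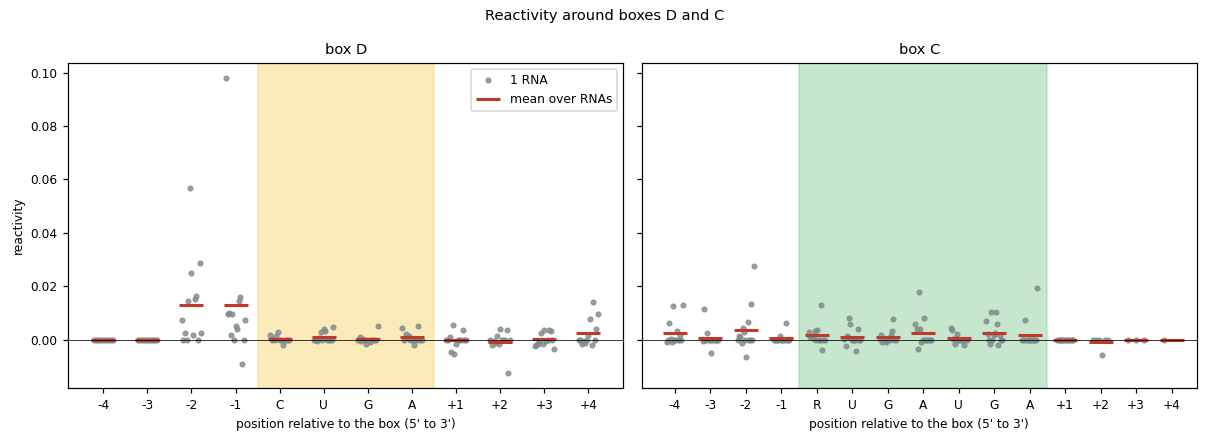
Reactivity score (y axis, no stated unit) at box D (13 RNAs) and box C (14 RNAs) and up to 4 nt on either side (x axis, position 5' to 3'), 1 point per RNA, with red lines at the mean over RNAs. Means are 0.0132 and 0.0129 at the 2 nucleotides before box D (0.00580 at the nearer one without bktRNA2) and at most 0.00274 within either box.

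Within box C, the U of position 2, which is extruded in known kink-turns, was compared with the G and A of positions 3 and 4, which take part in the sheared pairs. The mean score was 0.00104 ± 0.00312 (SD, 14 RNAs) at the U, 0.00101 ± 0.00224 at the G and 0.00259 ± 0.00535 at the A. The U was lower in 6 RNAs, higher in 4, and equal, at 0 on both sides, in the other 4. The mean difference was -0.000757 (SD 0.00425, exact permutation p = 0.514, adjusted p = 0.514), so no difference was detected. bktRNA133 alone held both internal boxes, UUGA at nt 37 and GUGAAGU at nt 65, and there the mean was 0.00973 in the boxes and 0.00599 elsewhere, untested with 1 RNA.

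The terminal 5 nt at both ends were lower than the rest in 11 of 14 RNAs, with a median contrast of -0.00429 (SD 0.00502, against -0.00188 in shifted profiles, permutation p = 0.117, adjusted p = 0.146). This did not pass the threshold, although medians, a cap and ranks each brought it past. With the always-zero positions treated as not measured, the contrast was -0.00231 (permutation adjusted p = 0.848, range over all settings 0.0123 to 0.848). The ends were not uniformly low. The third nucleotide from the 5' end averaged 0.0131 ± 0.0156 (SD, 14 RNAs) and was above 0 in 13 of them, while the fifth averaged 0.000388 ± 0.00110.

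Nucleotides predicted to be unpaired were more reactive than paired ones in 12 of 14 RNAs. In bktRNA16 the unpaired mean was 0.0279 against 0.00215 for paired nucleotides, in bktRNA4 0.0178 against 0.00184, and in bktRNA17 0.0135 against 0.00262. The order was opposite in bktRNA21 (0.00280 against 0.00611) and bktRNA2 (0.00628 against 0.00769). The median contrast was 0.00546 (SD over 14 RNAs 0.00757), against -0.000261 in shifted profiles, with a permutation p of 0.0002, the smallest the shifts can give, and an adjusted p of 0.001. The AUC had a median of 0.610 and ran from 0.382 in bktRNA21 to 0.743 in bktRNA4. The separation was lost among A and U alone (median contrast 0.00121, permutation adjusted p = 0.505, range over all settings 0.001 to 0.505).

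Among predicted hairpin loops, those with the highest mean were ACUGG of bktRNA16 (nt 29 to 33, mean 0.0634), AAAU of bktRNA17 (nt 30 to 33, mean 0.0587), UGCCAU of bktRNA4 (nt 44 to 49, mean 0.0448) and UUACU of bktRNA4 (nt 77 to 81, mean 0.0401). bktRNA105 held a reactive loop, CGA at nt 166 to 168 (mean 0.0340), and an unreactive one, CGGCAU at nt 91 to 96 (mean -0.00155). Over all RNAs the mean was 0.0206 ± 0.0258 (SD over 142 nt) in hairpin loops, 0.00977 ± 0.0177 (271 nt) in internal regions, 0.00498 ± 0.0138 (750 nt) in stems and 0.00398 ± 0.00820 in external regions, pooled over RNAs. Of the external nucleotides, 42 were always-zero end positions. Without such positions the external mean was 0.00623 ± 0.00957 (74 nt), above the 0.00508 ± 0.0139 (736 nt) of stems, so the order of these regions turned. The difference was not tested. Of the 41 nt above 0.05, many of them in bktRNA1, 18 were in hairpin loops, 8 in internal regions and 15 in predicted stems. The stem positions included the 4 highest of bktRNA1, at nt 128, 131, 145 and 218, which scored 0.169, 0.108, 0.104 and 0.101.

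**Figure D3:**
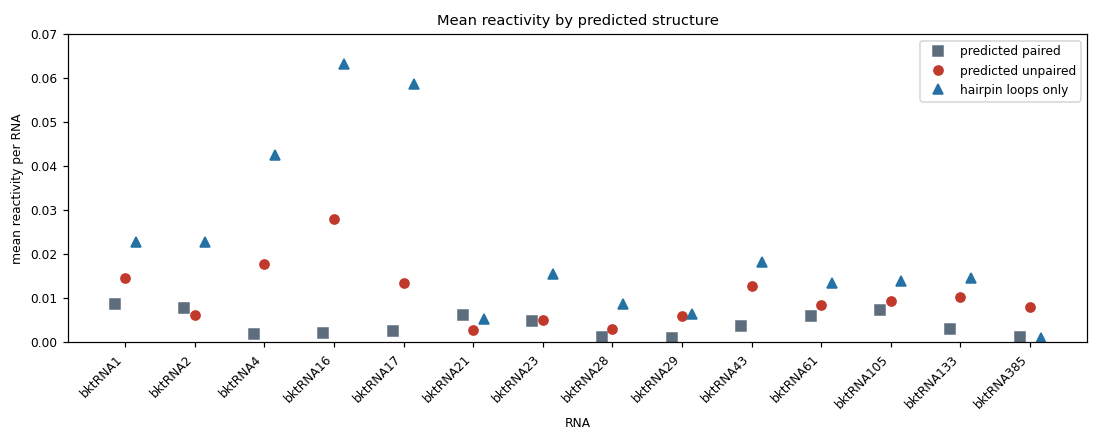
Mean reactivity score (y axis, no stated unit) of paired nucleotides (squares), unpaired nucleotides (circles) and hairpin loops (triangles) of the predicted structure in each of the 14 RNAs (x axis). Unpaired lies above paired in 12 of 14 RNAs, and hairpin loops reach 0.0634 in bktRNA16 and 0.0587 in bktRNA17.

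By base, C was below the mean of its RNA in 11 of 14 RNAs, with a median difference of -0.00224 (SD 0.00507, against -0.000349 in shifted profiles, permutation p = 0.0130, adjusted over 4 tests p = 0.0520). The exceptions were bktRNA21, bktRNA29 and bktRNA385. The latter pair, nearly identical in sequence, have their highest score at a C, and without bktRNA385 the median was -0.00232 and passed the threshold (permutation adjusted p = 0.0432, range over the 14 omissions 0.0432 to 0.0912). A was above its RNA's mean in 9 of 14 RNAs (median 0.00158, SD 0.00414, against -0.000522 in shifted profiles, permutation adjusted p = 0.0912), with the largest excess in bktRNA17 (0.0175 at A, 0.00796 over the RNA). U (0.000866, against -0.000363 in shifted profiles, higher in 10 of 14) and G (-0.000973, against -0.000190, lower in 8 of 14) had permutation adjusted p-values of 0.211 and 0.358. No base passed the threshold after adjustment, but C did with medians, with a cap and with ranks. C also passed against the other bases (-0.00313, permutation adjusted p = 0.0376, range over settings 0.0080 to 0.0912), a form computed first, by mistake, and replaced after its result was seen by the form fixed in advance. The base contrasts were not matched for predicted pairing, and 200 of the 307 C lay in predicted stems. Pooled over RNAs, C had the lowest mean of the bases in stems (0.00160) and hairpin loops (0.0136). In internal regions it had the highest (0.0117).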

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

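The settings that treat zeros or the first 2 and last 2 nt as not measured, leave out an RNA, move box D of bktRNA1, leave out boxes, keep G and C only or set a base against the other bases were chosen after the data were seen. No paired analysis was possible because there was 1 profile for the whole series and no value per library, and for the same reason no replicate could be left out. Of 73 tested settings other than leaving out an RNA, 56 kept direction and side of the threshold, 7 lost the call, 9 gained one, 0 reversed and 1 gave a value of 0 (G with medians). Of 3 values without a test, 2 were the same and the share of zeros moved to 21.8% without 5 nt at each end. Of 140 omissions of 1 RNA, 139 kept both and 1 gained a call. The box C contrast lost its call with medians (-0.000639), ranks (-0.103), zeros not measured (-0.00786) and 5 nt removed at each end (-0.00591), and box D with ranks (-0.150) and zeros not measured (-0.00759). Unpaired against paired lost it among A and U only (0.00121) and kept it among G and C only (0.00703). The terminal 5 nt gained a call with medians (-0.00136), a cap (-0.00398) and ranks (-0.118). Among bases, A gained one with a cap (0.00175), U with medians (0.00128), and C with medians (-0.000292), a cap (-0.00203), ranks (-0.0535), against the other bases (-0.00313) and without bktRNA385 (-0.00232). The causes were not tested. Zeros not measured, and 5 nt removed at each end, leave fewer box nucleotides. A and U only leaves fewer nucleotides, but so does G and C only, which kept the call. Setting missing values to 0 gave no value, because none was missing. Settings for the NAI-N3 against DMSO test, RNA classes, internal boxes and guide elements were not run. Depth was unknown, so what it limits could not be measured, although some scores recurred exactly, as given below.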

Other observations

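All tests in this part were chosen after the profiles were seen. Of the 11 explanations weighed, 10 have a p-value, and adjusted p-values are Benjamini-Hochberg values over those 10, except that the relation with length is adjusted over 2 relations. Tests at the ends were revised once the always-zero positions were noticed, and the bounds used to read several tests were made stricter or reworded after their values were seen. In their first form, the mean of the boxes minus other nucleotides within 15 nt of either end was -0.00190 (exact permutation p = 0.0167, lower in 10 of 14 RNAs), and the terminal 5 nt at both ends held 35.0 percentage points more zeros than the rest (exact permutation p = 0.000122).

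Hairpin loops stood out among unpaired nucleotides. They were more reactive than the other unpaired nucleotides of the same RNA in 13 of 14 RNAs, by a median of 0.00936 (SD 0.0180, against -0.00139 in shifted profiles, permutation p = 0.0002, the smallest the shifts can give, adjusted p = 0.001). The gap was widest in bktRNA17 (0.0587 in hairpin loops, 0.00626 in other unpaired nucleotides) and bktRNA16 (0.0634 and 0.0118). In bktRNA385 the order was opposite (0.00103 and 0.00942). With boxes C and D left out, the median was 0.00692. The contrast between unpaired and paired nucleotides may thus come in part from hairpin loops, a hypothesis made and tested on the same profiles.

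bktRNA1 differs from the other RNAs in layout. Its nt 1 to 146, which overlap SNORA12, averaged 0.0116 ± 0.0253 (SD over nucleotides) and held 15 nt above 0.05. The remaining 105 nt averaged 0.0102 ± 0.0150 and held 3. The last CUGA before its box C lies at nt 221 to 224 and averaged 0.00568, the 19 nt between averaged 0.00853, and box C averaged 0.00301. Longer RNAs had higher mean reactivity (14 RNAs, Pearson r = 0.625, permutation p = 0.0160, adjusted 0.0210, and Spearman rho = 0.695, permutation p = 0.00744, adjusted 0.0149, 2 relations computed). Without bktRNA1 and bktRNA105, r was 0.404 (12 RNAs, permutation p = 0.198) and rho 0.564 (permutation p = 0.0590). The linear relation thus rests on those RNAs, while the rank relation fell less and missed the threshold. The mean of each RNA includes its first 2 and last 2 nt, which are always 0. These positions are a larger share of a short RNA and lower its mean by a larger fraction. The relation was not computed without the ends, so how much of it rests on them is unknown.

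Boxes C and D were low, and the values argue against some technical explanations, in a simple form, when exact zeros are counted as scores. Zeros that stand for no estimate stay open as an explanation, at least in part. The median over RNAs was 0 at each position of box D, and both box calls were lost with zeros treated as not measured. The contrasts were then -0.00786 for box C (permutation adjusted p = 0.0690) and -0.00759 for box D (permutation adjusted p = 0.146). Box D minus the 2 nt before it, which lie nearer to the 5' end, was -0.0128 in the mean (SD 0.0143, lower in 12 of 13 RNAs, exact permutation p = 0.00195, adjusted 0.00391). Only nt 3 was used in bktRNA4 and bktRNA17, where nt 2 is always 0. Without bktRNA2 the mean was -0.00957 (lower in 11 of 12, exact permutation p = 0.00391). These values argue only against a loss of signal that deepens steadily from box D towards the end. Box D lay at nearly the same distance from the 5' end in all 13 RNAs. An effect of that distance and an effect of the box thus cannot be told apart. Box nucleotides predicted to be unpaired were lower than other unpaired ones (-0.0140, lower in 14 of 14, exact permutation p = 0.000122, adjusted 0.001), and boxes were lower than their bases elsewhere would give (-0.00718, lower in 13 of 14, exact permutation p = 0.000366, adjusted 0.00122), so predicted pairing alone and base composition alone do not account for all of it. Neither comparison was matched for the kind of region or the distance from the end. The other unpaired nucleotides include hairpin loops (pooled mean 0.0206), while external regions averaged 0.00623 without always-zero positions. A loss of signal at the 3' end stays open for box C, which did not differ detectably from the other nucleotides of the last 15 (0.000627, lower in 5 of 14, exact permutation p = 0.365, adjusted 0.457). The low signal did not end at the inner edge of the boxes, where the next 4 nt did not differ detectably from them (0.000314, bootstrap 95% interval -0.000773 to 0.00138, exact permutation p = 0.586, adjusted 0.586). Scores were higher just outside the outer edge of box D, but that edge coincides with a nearly fixed distance from the end. Protection by SNU13 was not tested, because no sample used here was probed without the protein.

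The share of exact zeros ran from 1.59% in bktRNA1 and 6.67% in bktRNA16 to 53.2% in bktRNA28. Nt 3 to 10 from each end, which hold most box nucleotides, had 22.1 percentage points more zeros than the nucleotides further in (43.8% against 21.6%, exact permutation p = 0.00391). Outside the boxes the excess was 40.9 points at the 3' end (29 nt, opposite in 2 of 14 RNAs, exact permutation p = 0.00195, adjusted 0.00391). In most RNAs the nucleotides counted there were only nt 9 or 10 from the 3' end, on the inner side of box C. Zeros did not grow steadily towards that end, with 10 of 14 RNAs at 0 at nt 9 and 6 at nt 3. Whether some zeros mark a poorly measured 3' end thus cannot be told from this excess. At the 5' end the excess outside the boxes was 5.18 points (60 nt, exact permutation p = 0.429, adjusted 0.477). With boxes counted, 1 RNA of 14 was at 0 at nt 3 from the 5' end and 4 at nt 4. The latter include bktRNA4 and bktRNA17, whose nt 4 is the C of box D. In the inner part, paired nucleotides held 10.5 points more zeros than unpaired ones (exact permutation p = 0.0376, adjusted 0.0627), which fails the adjustment. A coarser profile in some RNAs, as low depth would give, stays open. Over 14 RNAs the share rose with the smallest non-zero score (Spearman rho = 0.546, permutation p = 0.0458, adjusted 0.0655, which fails the adjustment). Pearson r on its log10 was 0.603 (permutation p = 0.0210). Without bktRNA1 and bktRNA385 the rho was 0.319 (12 RNAs, permutation p = 0.312) and r 0.306, so the relation rests on those RNAs. An RNA with more non-zero scores tends to have a smaller minimum, so part of the relation is built in. Some scores recurred exactly, such as 0.013158 at nt 35, 37 and 42 of bktRNA385 and 0.050584 at nt 62 and 166 of bktRNA105. Coarse scores would give such repeats, but the reads behind them were unknown.

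bktRNA29 on chromosome 1 and bktRNA385 on chromosome 10 are identical over their first 52 nt (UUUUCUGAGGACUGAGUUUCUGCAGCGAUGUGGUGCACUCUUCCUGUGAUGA). Their profiles had r = 0.895 across the nucleotides of this stretch, which are not independent replicates, and 0.582 without the shared peak at nt 36. Reads shared between the loci may contribute, but no non-zero score was exactly equal, 17 nt were 0 in both, and the slope of bktRNA385 on bktRNA29 was 1.61, so shared reads and a like structure cannot be told apart from these values. bktRNA23 and bktRNA105 share 32 nt, over which r was 0.401. In the tests over RNAs, bktRNA29 and bktRNA385 were counted as separate RNAs, although they are nearly identical in sequence.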
